A study of Homo sapiens with 6 samples.

How the data were processed

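Per the labels, RNA of 3 human myeloma cell lines, each cultured with and without C-reactive protein, had been hybridised to 1-colour Illumina bead arrays. Per the labels' protocols, total RNA was extracted with TRIzol, purified on RNeasy columns, amplified and labelled with biotin. The deposited un-normalized table gives, per the file headers, an average signal and a detection p for each probe and array. The authors' signal is an intensity on a linear scale, without background subtraction or normalization as far as the values show. The deposited detection p-values ran in steps of 1 in 770, as ranks among that many negative-control beads would, except for 5 of 283158 values on 2 probes (those of CCL2 and TWIST1). A processed value table with 47189 of the 47193 probes was used as an alternative. Its scale, not given in the sources used here, was found from the values: its intensities were linear, about 52.4 to 55.2 units below the signals, with medians of 7.17 to 7.19 and a common maximum of 21735.5 on all 6 arrays, as after background subtraction and quantile normalization. GenomeStudio is the tool that the submitters' processing notes name, and its version is not given in the sources used here.

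Arrays were grouped by the labels into 3 control and 3 CRP arrays, 1 of each per line. Signals were background-corrected and normalized with limma 3.58.1 on R 4.3.3 by its neqc procedure (a normal-exponential model with background taken from the detection p-values, offset 16, quantile normalization, log2). Gene names came from the table's own symbol column and were brought up to date with a RefSeq table of assembly GRCh38.p14, used for names alone and with no coordinates printed. Of the probes, 26998 had a current symbol, 4675 were renamed through a synonym, 12250 kept a name that the table did not hold, and 3270 had no gene name. The 30843 gene names included 8664 with more than 1 probe, and the probe with the highest mean stood for its gene. Genes were kept where the detection p was under 0.01 on at least 3 of 6 arrays, which left 10959 of them.

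Each deposited signal was checked against its detection p and against the rank of the same probe in the processed table. A probe was called discordant where its ranks differed by more than 50 places. The range of signals of other probes at the same detection p gave the signal that a detection p implied. Discordant probes were kept in the fits and marked at each value, and were left out in an alternative.

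CRP and control were compared with limma's lmFit and eBayes with the line as a block, two-sided, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The line pairs the arrays by design. Deviations from the treatment means correlated between the arrays of a line with r of -0.10, -0.01 and 0.07 in ARP-1, MM.1S and U266, and with -0.15 to 0.17 between arrays of different lines. The lines were compared by limma's moderated F test and 3 contrasts with treatment as a covariate. Within a line there was no test, and genes detected on at least 1 of the 2 arrays were counted past 1.5-fold. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and each list's median in a line was ranked among 10000 random lists matched on mean expression in 20 bins. A gene not detected on any array of a group was given a bound: the mean log2 level of the brighter group minus that of the dimmer group, in which each array counted at the higher of the probe's level and the lowest level among detected probes.

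Except for fry's test for changes in either direction, the groups, tests, alternatives, 31 lists and the rule for named genes were set before the data were examined. That rule took the 12 genes higher and the 12 lower in all 3 lines with the largest smallest-of-3 change, all genes past the threshold, up to 4 kept members of each list by mean change, the cytokines, the 4 genes of the title, the 8 highest and 8 lowest genes within a line, and myeloma oncogenes for the lines. Not all of these are printed, and a few genes are not reported here. Where discordant probes held some of the 12 places, the same ranking was also taken over concordant genes. Besides those lists named by pathway in the report, 7 lists held markers of monocytes and macrophages, T and NK cells, mature B cells, stromal cells, osteoclasts, erythroid cells and epithelial cells. Lists with fewer than 3 kept genes (7 of 31) were not tested. CDK1 and MZB1 of the lists were not matched by name on the array. Levels of plasma cell genes, cell type markers and discordant probes were described after their values were seen.

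The gene and list tests were tried on simulated data made from the arrays' means and spread, with 200 of 10959 genes changed, or 5 lists shifted, in each of 10 runs. For CRP against control, 0% of genes changed by 1.5-fold were recovered, 95.7% (SD 0.919) of those changed by 2-fold and 99.8% of those changed by 4-fold. For the lines the shares were 0%, 85.1% (SD 5.33) and 99.1%. Lists shifted by 0.1, 0.2 and 0.4 on the log2 scale were recovered in 74%, 94% and 100% of cases. Simulated genes varied independently of each other, whereas the correlation estimated on the arrays reached 0.18 for the cytokine list. Recovery of correlated lists may be lower. The comparison of ranks was tested in 1 run on 47145 probes, 200 of them multiplied by 0.6, and found 97% of these and no others, at a wider limit than the 50 places used on the deposited values.

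Alternatives covered background correction, normalization, the filter on dim probes, the choice of probe, the processed table, the model and each left-out line. An alternative with the slide as a block was not run, since the sources used here give no slide. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for tables and plots.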

Results

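Transcript levels were measured on 6 Illumina bead arrays, each carrying 47193 probes, in cells labelled as human multiple myeloma lines. Myeloma is a cancer of plasma cells, the antibody-secreting end stage of the B lineage, and ARP-1, MM.1S and U266 are established lines of it. By the labels, each line was represented by 1 control array and by 1 array of cells given 5 µg/ml C-reactive protein (CRP) for 24 h, so that 3 control and 3 CRP arrays could be compared with the line as a block. The levels of line-specific genes did not bear out the line labels, and line names below are those of the labels. CRP is a liver-derived acute-phase protein of blood plasma that binds Fc-gamma receptors. Median signals lay between 59.2 and 62.5 intensity units. Probes with a detection p under 0.01 numbered 13906 on the ARP-1 control array and 15164 on its CRP array, 14306 and 14828 on those of MM.1S, and 14390 and 14664 on those of U266. The small number of arrays limits the precision of every value. Nothing in the labels describes repeated cultures of a line, so p-values measured the spread of the CRP difference between the 3 lines' arrays.

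The plasma cell identity of the material was plain on every array. Of 24 measured plasma cell genes, 20 were detected on all 6 arrays, among them JCHAIN, the joining chain of secreted antibody, with a mean signal of 8822 in control and 8486 in CRP cells. XBP1, a transcription factor of secretory cells, had 7787 and 8583, SDC1 (the plasma cell antigen CD138) 1472 and 1567, PRDM1 2798 and 2639, IRF4 614 and 608, and TNFRSF17 (BCMA) 2797 and 2800. CD27, CD79A and TNFRSF13B were detected on no array. Markers of other cell types were mostly undetected on all 6 arrays: 9 of 14 for monocytes and macrophages, 10 of 12 for T and NK cells, 10 of 12 for mature B cells, 11 of 12 for stromal cells, 7 of 9 for osteoclasts, 8 of 10 for erythroid cells and 6 of 8 for epithelial cells. The exceptions detected on all 6 arrays included CD68, AIF1, VCAN, HLA-DRA, COL6A3 and CTSK.

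For 44 probes of 43 genes the deposited values did not belong together. On the other 47149 probes, signal and detection p ran in the same order on every array, and the rank of a probe in the un-normalized table differed by at most 39.5 places from its rank in the authors' processed table. On the 44 probes that difference was at least 1276 places, and 189 of their 264 signals lay outside the range of signals that other probes with the same detection p had on the same array, 186 of them below it. For 5 of these signals the detection p was off the steps of 1 in 770, and the nearest step gave the range. Where that range was narrower than 1 intensity unit, 96 of 123 such signals lay a whole multiple of 10 units from it, against 2.24 given by the widths of the ranges. These distances were 20 units for 5 signals, 30 for 16, 40 for 33, 50 for 25 and 60 for 17. The genes concerned included TWIST1, the cytokine genes CCL2, CCL3, CSF1, HGF, IL1A, IL6, IL11, IL17A, TNFSF11 and TNFSF13B, the decoy receptor gene TNFRSF6B, and GTF2H2, KAT7 and other genes, mostly of transcription factors: ELK4, FOXC2, FOXD4L1, FOXD4L2, HOXC6, HOXD4, JDP2, LHX5, MTF2, MXI1, NR4A2, POU2F3, RFX2, RFX3, SEBOX, SOX4, SOX8, SOX9, SP4, TFDP2, THAP2, ZEB2, ZNF134, ZNF136, ZNF16, ZNF2, ZNF223 and ZNF234. They are called discordant probes here, and the remainder concordant.

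On the discordant probes signal and detection p differed in how they went with treatment. The signal was higher with CRP in all 3 lines on 34 of the 44, and the processed value on 41, while the detection p was lower with CRP in all 3 lines on 6, TWIST1, CCL2 and TNFSF11 among them. Of all detection p-values, 5 were not multiples of 1 in 770 as the others were, and these belonged to CCL2 (all 3 CRP arrays) and TWIST1 (2 arrays). Among concordant probes, 12.5% had a higher signal in all 3 lines and 9.81% a lower detection p. Signals below the lowest concordant signal of their array made up 94 of 132 on control arrays and 50 of 132 on CRP arrays. Over the 36 discordant probes with a detection p above 0 on both arrays of at least 1 line, the log2 change with CRP had a median of 1.06 (SD 0.634) by signal. The change implied by their detection p had a median of 0.01 (SD 0.135).

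**Figure D1:**
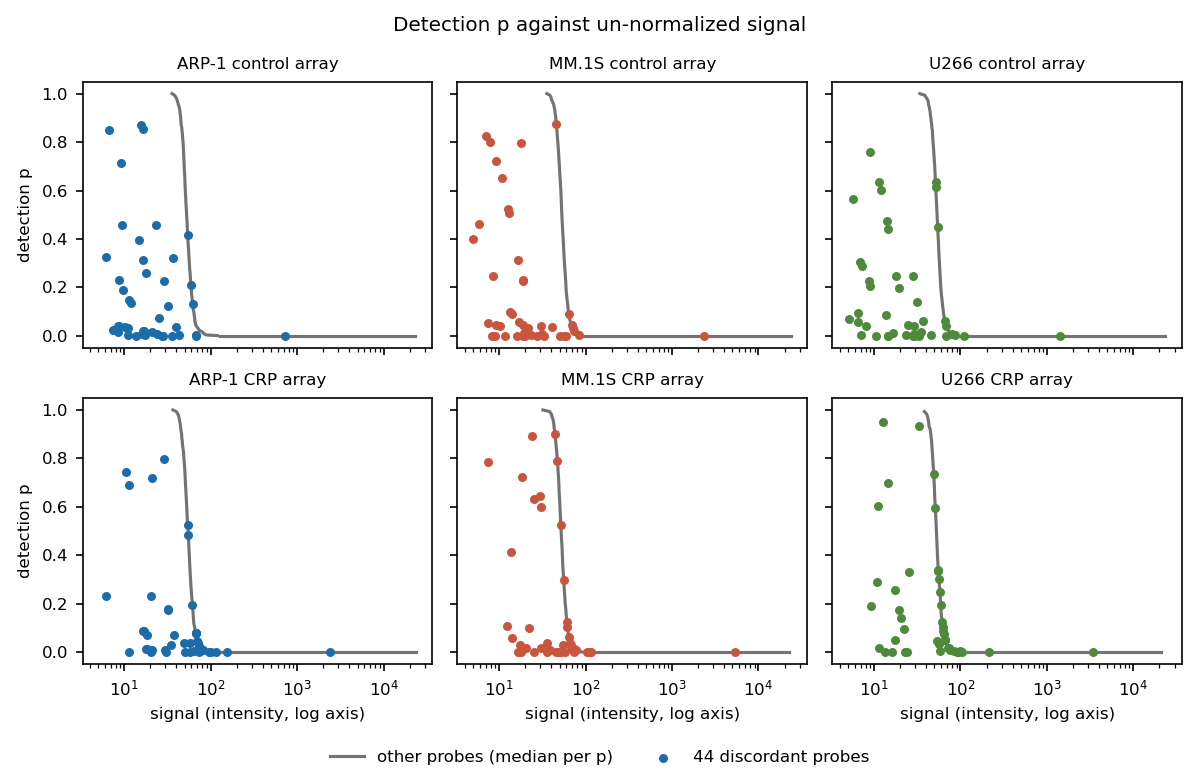
Detection p (vertical axis) against un-normalized signal in intensity units (horizontal log axis) on each of the 6 arrays, with the grey line at the median signal of concordant probes at each detection p and the 44 discordant probes as points. Of 264 discordant signals, 186 lay below the signals that other probes with the same detection p, or the nearest step of it, had.

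The first comparison asked which transcripts differed between cells given CRP and control cells, and the title of the series directs it at bone-destroying cytokines. The threshold was passed by 5 genes, all with higher signals in CRP cells and all measured by discordant probes, and by 0 genes without the arrays of ARP-1 or without those of MM.1S. CCL3, which encodes the osteoclast-activating chemokine MIP-1-alpha, had a mean signal of 1502 ± 827 in control and 3729 ± 1535 in CRP cells (SD, n = 3), a log2 difference of 1.42 (SE 0.119, limma adjusted p = 0.0347). In the authors' processed values it had 1049 ± 434 and 1555 ± 533 and did not pass, nor did CCL3 and ZNF223 pass with no replicate block, where 4 genes were called. The zinc finger gene ZNF223 had a signal of 78.4 ± 28.4 in control and 160 ± 51.7 in CRP cells, ZNF134 49.1 ± 8.82 and 97.8 ± 15.9, and ZNF2 62.3 ± 10.5 and 108 ± 5.46, with adjusted p of 0.0198, 0.0198 and 0.0347. Detected concordant probes had signals of at least 75.3 to 83.1, depending on the array. The control signals of ZNF134 and ZNF2 were lower than that, as were those of ZNF223 in ARP-1 (67.7) and MM.1S (56.9). Their detection p was under 0.01, so these signals were too low for their p, and no fold is given for these genes. KAT7, a histone acetyltransferase gene, had a signal of 22.6 ± 6.30 in control and 72.7 ± 3.47 in CRP cells (adjusted p = 0.0347), although by detection p it was detected on the 3 control arrays and on none of the CRP arrays, so no fold is given. Its control signals of 16.1, 23.1 and 28.6 became log2 levels of 4.16, 4.18 and 4.18 at the floor of the normalized scale. The p of KAT7 thus does not measure the spread of its signals. FOXD4L1, a forkhead gene on a discordant probe, did not pass (adjusted p = 0.0708), but passed under 5 alternatives (normexp, no background correction, median scaling, genes detected on all 6 arrays and no replicate block). Its control signals of 27.2 to 33.3 were too low for its detection p, which was 0 on all 3 control arrays. Its processed control values were 174, 142 and 182 in ARP-1, MM.1S and U266, and the processed value was higher with CRP in 1 line.

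No gene measured by a concordant probe passed the threshold among 10945 such genes (limma, smallest adjusted p 0.134), and 660 of them (6.03%) had an unadjusted p under 0.05. Over all 10959 genes, 668 had an unadjusted p under 0.05, 315 higher and 353 lower, where 548 would come by chance. The median absolute log2 change of concordant genes was 0.08. A typical gene had a 95% interval of 1.18-fold either way, before adjustment for many genes, and 16 concordant genes had a mean difference of at least 1.5-fold, 6 higher and 10 lower. In simulated data the adjusted test recovered 0% of genes changed by 1.5-fold, so changes of that size could go uncalled. The direction was shared by all 3 lines in 26.9% of genes, with 25% given by chance. Without the discordant probes no gene passed, and with the authors' processed values in place of the signals none passed either, with or without those probes.

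Of the concordant genes lower with CRP in all 3 lines, FCGR3A, which encodes the low-affinity IgG receptor CD16A, had the largest of the smallest changes. It was detected on 3 arrays, all of control cells, and was at least 1.25-fold lower in CRP cells (adjusted p = 0.134). RNF128, a ubiquitin ligase gene, was likewise detected in control cells alone, at least 1.20-fold lower (adjusted p = 0.246). FRRS1 differed by -0.70, TCEAL9 by -0.66, the cell cycle transcription factor gene E2F1 by -0.65, LOC647971 by -0.49, LOC100131866 by -0.48, GTPBP10 by -0.45, AAMP by -0.44, SH3RF3 by -0.43, LOC100129211 by -0.42 and LOC100132585 by -0.36, each with an adjusted p of 0.749. Of these, E2F1 and LOC647971 were detected on 3 arrays, TCEAL9 on 4, GTPBP10 on 5 and the others on 6. TCEAL9 had -1.20 in ARP-1, -0.35 in MM.1S and -0.43 in U266. Among concordant genes higher in all 3 lines, FLJ42258 was detected in CRP cells alone and was at least 1.37-fold higher (adjusted p = 0.253). MIR22HG, the host transcript of a microRNA, differed by 0.60, with 0.55, 0.64 and 0.61 in ARP-1, MM.1S and U266 (adjusted p = 0.315). MGC2752 differed by 0.75, CNPY4 by 0.54, L3HYPDH by 0.53, the growth factor gene PDGFC by 0.49, LOC642732 by 0.48, the splicing kinase gene CLK4 by 0.46 and LOC730153 by 0.45, none past the threshold. Of these, MGC2752, L3HYPDH, PDGFC and LOC730153 were detected on 4 arrays and the others on 6. BDP1, BTBD9 and MMS22L, not detected on control arrays, were at least 1.16, 1.06 and 1.03-fold higher (limma adjusted p = 0.749, 0.749 and 0.684). Like FCGR3A, RNF128 and FLJ42258, these genes passed the filter of 3 arrays through 1 treatment alone. Their bounds are point values without an error.

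**Figure D2:**
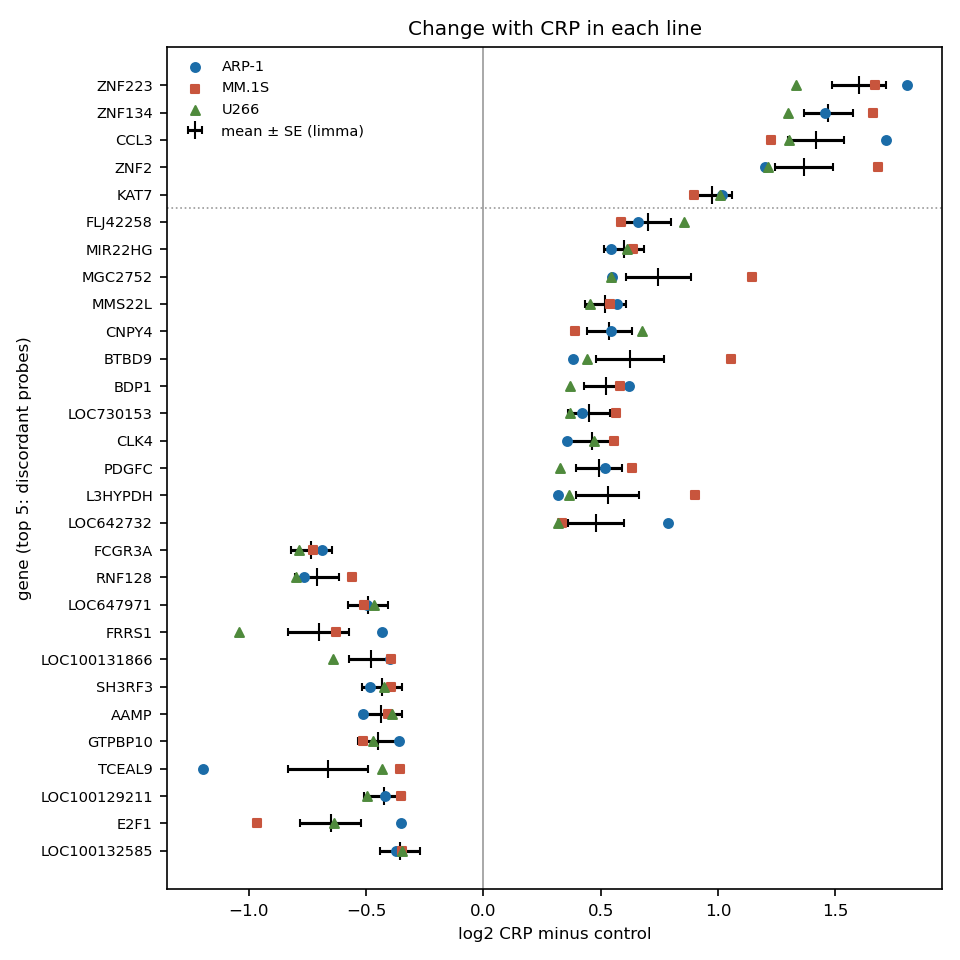
Log2 change with CRP (horizontal axis) of the 5 genes past the threshold, above the dotted line and on discordant probes, and of the 24 named concordant genes below it, with each line as a coloured point and the mean as a black mark with its standard error (limma). As fitted, FCGR3A differed by -0.73, FLJ42258 by 0.70 and CCL3 by 1.42. The fitted values of the other genes above the dotted line rest mostly on control signals below those of detected concordant probes.

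None of the 4 genes of the signalling axis in the title of the series passed the threshold, and TWIST1 and FCGR2A were too dim to enter the test. FCGR2A, which encodes the Fc-gamma receptor CD32A, was not detected on any array by any of its 4 probes, and its leading probe had a signal of 57.8 ± 2.84 in control and 57.0 ± 5.22 in CRP cells (SD, n = 3). The closely related inhibitory receptor gene FCGR2B was detected on all 6 arrays by 1 of 3 probes, at 97.6 ± 11.4 and 90.5 ± 5.94, a log2 difference of -0.16 (adjusted p = 0.906). MAPK14, which encodes the stress kinase p38-alpha, was detected on all 6 arrays by 2 of 4 probes and had 105 ± 4.59 and 106 ± 17.5, a difference of 0.00 (SE 0.111). TWIST1, a basic helix-loop-helix transcription factor gene, has a single probe, and it was discordant. Its signal was 23.2 ± 1.48 in control and 56.7 ± 0.786 in CRP cells. All 6 signals lay below those of other probes with the same detection p, or with the nearest step where its own was off the steps. Its detection p was 0.457 in control and 0.0379 in CRP cells of ARP-1, 0.0325 and 0 in MM.1S, and 0.0449 and 0.0325 in U266. Both measures went the same way in all 3 lines, but in ARP-1 and U266 the detection p did so through the 2 values off the steps of 1 in 770, and by detection p it was detected on 1 array.

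Cytokines that act on osteoclasts, the cells that resorb bone, were mostly below detection in these lines. Of 30 measured, 20 were read by a concordant leading probe, and 13 of those were detected on no array. CCL5, a chemokine gene, was detected on all 6 arrays at a mean signal of 2623 in control and 2453 in CRP cells, ADM, which encodes adrenomedullin, at 2702 and 2907, and CCL3L1, a near-identical copy of CCL3, at 366 and 358, with log2 differences of -0.10, 0.10 and -0.05. The other 10 were read by discordant probes, and 9 of these had a higher mean signal with CRP, including TNFSF11 (RANK ligand) with 18.7 and 67.5 and CCL2 with 13.7 and 52.6, while IL6 was the exception. The detection p of TNFSF11 and CCL2 was also lower with CRP in all 3 lines, though for CCL2 through the 3 values off the steps of 1 in 770, and for TNFSF11 in U266 only from 0.603 to 0.596. By detection p, 7 of these 10 were detected on no array. Among the 20 concordant cytokines the mean signal was higher with CRP in 12, and log2 ratios of the means ranged from -0.18 to 0.31. Of the 8 cytokines bright enough to test, 1 (CCL3) passed over all genes and adjusted over the list alone, and the others included LTA at 0.23, IL11 (discordant) at 0.24, CXCL8 at -0.15 and VEGFA at -0.10. Inhibitors of bone-forming osteoblasts were undetected on all 6 arrays in 13 of 14 cases, among them DKK1 with signals of 61.8 and 66.3, and none could be tested.

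**Figure D3:**
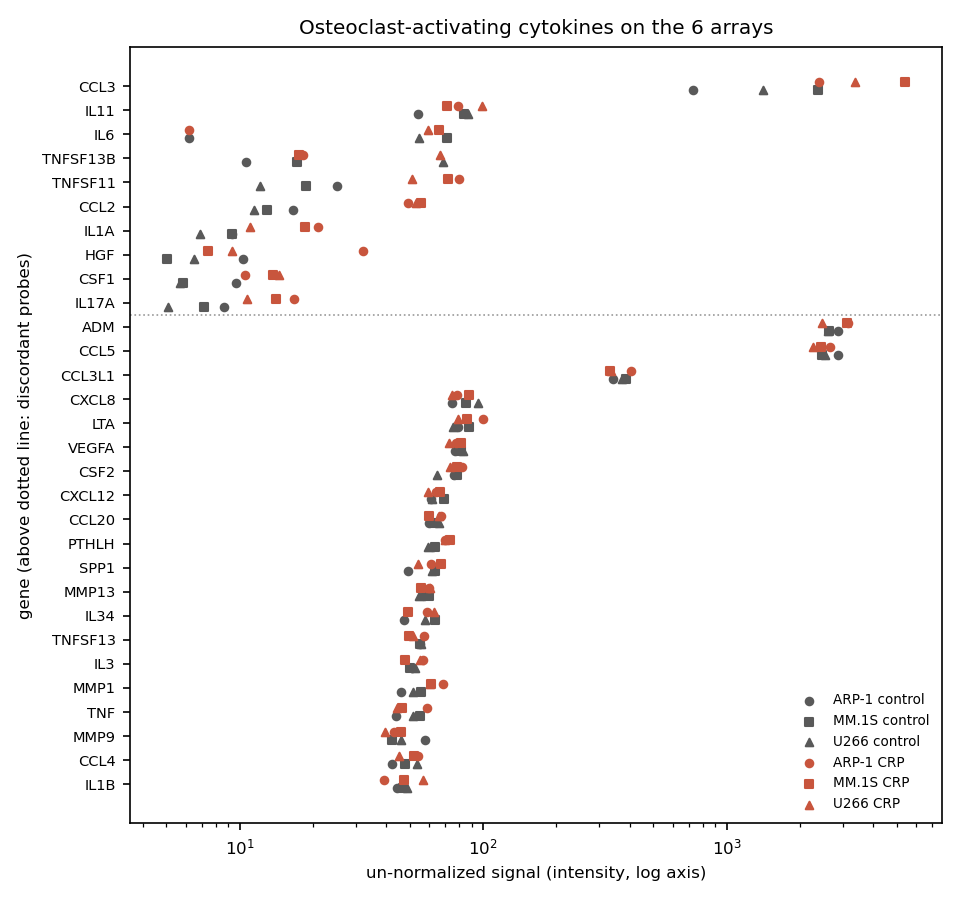
Un-normalized signal in intensity units (horizontal log axis) of 30 osteoclast-activating cytokines, with each array as a point, grey for control and red for CRP, the marker shape giving the line, and discordant probes above the dotted line. Concordant cytokines had log2 ratios of CRP over control between -0.18 and 0.31, and discordant TNFSF11 had mean signals of 18.7 and 67.5.

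None of 24 gene lists with at least 3 kept genes passed the threshold (camera, smallest adjusted p 0.440, 1 list with an unadjusted p under 0.05), nor with an estimated correlation (smallest adjusted p 0.980) or in fry's directional test (smallest adjusted p 0.315). The lists' median log2 changes lay between -0.05 and 0.06, and 23 of 24 held no member past the threshold over all genes. Fry's test for changes in either direction was not named in the plan and compares a list with no other genes. It called the list of Fc-gamma receptor signalling (adjusted p = 0.0175). The list's 12 kept members had a median of -0.04, and 1 was higher and 3 were lower in all 3 lines. Of the 12, 2 had an unadjusted p under 0.05 (limma), and FCGR3A passed when adjusted over the list alone. FCGR3A was kept through its 3 control arrays, the only ones to detect it. The list was not tested without FCGR3A, so the call shows no change of the list as a whole. Other leading members were INPP5D, a phosphatase gene, at 0.26 and FCGRT, the neonatal Fc receptor gene, at -0.26. Genes of the p38 pathway were detected on all 6 arrays in 26 of 31 cases and had a median of 0.01, with DUSP1, a phosphatase gene that acts on p38, at 0.22 and HSPB1 at -0.20. Of 20 genes of TWIST and epithelial-mesenchymal transition, 7 were kept, with a median of 0.06, the highest of the 24 lists. Of the 7, 4 were higher and 0 lower in all 3 lines. The adjusted p was 0.837 by camera and 0.053 by fry's test for either direction. CTNNB1 (beta-catenin) had 0.22, BMI1 0.16, TCF3 0.11 and TCF4 -0.08, and the mean signal of VIM (vimentin) was 11219 in control and 10984 in CRP cells.

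Genes of the amino acid response under ATF4 gave the smallest camera p of the lists. Their median was -0.05 over 25 kept members, 6 lower and 1 higher in all 3 lines, with PSPH, an enzyme gene of serine synthesis, at -0.38. The early response genes had a median of -0.01 over 18, although FOS had the largest fitted difference of any list member on a concordant probe, 0.84 (adjusted p = 0.749), with 1 of 3 control arrays and 3 of 3 CRP arrays detecting it. Interferon response genes had a median of -0.02 over 22, with BST2 at -0.27 and IFI44 at -0.26. Cholesterol synthesis had -0.03 over 22, with CYP51A1 at -0.26. Proliferation genes had 0.04 over 34, with RRM2 at -0.31 and MKI67 at -0.26, and p53 targets -0.03 over 13, with BBC3, a cell death gene, at -0.30. The unfolded protein response had -0.02 over 21 members, with XBP1 at 0.16, and heat shock genes 0.00 over 19, with HSPA1A at -0.41. Targets of NF-kappa-B had 0.04 over 17 members, STAT3 and interleukin 6 response genes -0.01 over 12 with STAT3 at -0.23, and the BCL2 family -0.02 over 12. Hypoxia and glycolysis genes had 0.01 over 23, metallothionein and oxidative stress genes 0.02 over 15, ribosomal proteins -0.03 over 37 and replication-dependent histones 0.01 over 13. Plasma cell genes had -0.01 over 20, myeloma oncogenes and translocation targets -0.01 over 19 with CCND3 at -0.20, bone homing and adhesion genes 0.03 over 12 with CCR10 at -0.26, complement and acute-phase binding genes 0.01 over 5, and monocyte markers -0.05 over 3.

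On the pair of arrays labelled ARP-1, 503 of 11546 detected genes differed by at least 1.5-fold, 279 higher and 224 lower with CRP. LOC728253 was at least 4.35-fold higher and CLDN4, a tight junction gene, at least 1.62-fold higher. LOC100129882 had -1.99, the muscle caveolin gene CAV3 was at least 2.14-fold lower and the autophagy gene GABARAP at least 1.97-fold lower. On the arrays labelled MM.1S, 458 of 11466 genes differed by that much, 251 higher and 207 lower. FOS, part of the AP-1 transcription factor, was at least 2.69-fold higher and the integrin gene ITGA2 at least 1.35-fold higher, while PLEKHG5 and IMPA1 had -1.36 and -1.35 and TELO2 was at least 2.42-fold lower. On the arrays labelled U266, 554 of 11477 genes differed, 291 higher and 263 lower. The highest there were HOXD4, FOXD4L1 and SOX4 on discordant probes. LMTK2, MATK and NPR1, of which the first pair encode kinases and the last a natriuretic peptide receptor, were at least 1.55, 1.21 and 1.22-fold lower. A single array per treatment allowed no test. The counts of 503, 458 and 554 became 162, 120 and 133 with genes detected on all 6 arrays, 79, 63 and 74 without background correction and 44, 31 and 35 with normexp at an offset of 50. They became 778, 752 and 892 with no filter and 789, 756 and 885 with a detection p under 0.05 as the filter.

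Most of these differences were not shared between the 3 pairs of arrays. With 1 array per treatment and labels not borne out, this cannot show whether lines differed in their response. Across concordant genes, the changes of ARP-1 and MM.1S correlated with r = -0.01, those of ARP-1 and U266 with r = 0.02 and those of MM.1S and U266 with r = 0.07, and genes are not independent replicates. Concordant genes past 1.5-fold the same way in both lines numbered 9, 20 and 11 in these pairs, above the 3.08, 3.70 and 3.17 of independent lists. Genes past it in opposite ways numbered 14, 13 and 16, for which no such figure was computed. No concordant gene detected in both treatments was past 1.5-fold the same way in all 3 pairs. FCGR3A and FLJ42258 were so as normalized, but each was undetected on all 3 arrays of one treatment, with bounds of 1.25 and 1.37-fold. Of 72 list medians by line, 3 lay outside the central 95% of 10000 matched random lists, where 3.6 would come by chance. All 3 were low in U266: the ATF4 list at percentile 0.02, cholesterol synthesis at 1.77, and the p53 targets. The ATF4 list lay at percentile 89.5 in ARP-1 and 3.14 in MM.1S.

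The lines were compared next, with treatment as a covariate. CCND1 and MAF, which separate U266 and MM.1S by textbook knowledge, did not separate the arrays labelled with their names. CCND1, the cyclin D1 gene that is rearranged and active in U266, had mean log2 levels of 8.01 on arrays labelled ARP-1, 8.10 on those labelled MM.1S and 8.03 on those labelled U266, and U266 minus MM.1S was -0.07 (95% interval -0.38 to 0.23). MAF, the transcription factor gene translocated in MM.1S, had mean signals of 2248, 2237 and 1916, and U266 minus MM.1S was -0.14 on the log2 scale (-0.40 to 0.11). MYC had mean signals of 4135, 4152 and 3648. FGFR3, a receptor gene activated by another myeloma translocation, had log2 levels of 5.25, 5.56 and 5.24. Its mean signals of 77.6, 84.6 and 73.9 were near the lowest of detected probes. The tumour suppressor gene CDKN2A had log2 levels of 9.60, 9.56 and 9.32. No line is named here as the one to differ in MYC, FGFR3 or CDKN2A, so these genes do not bear on the labels.

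No gene passed the F test over the 3 lines (limma, smallest adjusted p 0.286). By the same test 535 genes (4.88%) had an unadjusted p under 0.05, where 548 would come by chance. The pairwise contrasts called none either, with 445, 527 and 613 genes at an unadjusted p under 0.05 for MM.1S against ARP-1, U266 against ARP-1 and U266 against MM.1S. The smallest p of the F test belonged to ZNF223 and CCL3, both on discordant probes, and to the mitochondrial transcript MIR1974, which was higher by 1.21 in MM.1S than in ARP-1. A typical line difference had a 95% interval of 1.22-fold either way, before adjustment, and 0% of line differences of 1.5-fold were recovered in simulated data. Arrays of the same line differed by an SD over genes of 0.231 ± 0.00520 on the log2 scale (SD, n = 3 pairs) and arrays of different lines by 0.227 ± 0.0110 (n = 12 pairs), with 17.3 ± 1.15 and 13 ± 4.37 genes past 2-fold.

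**Figure D4:**
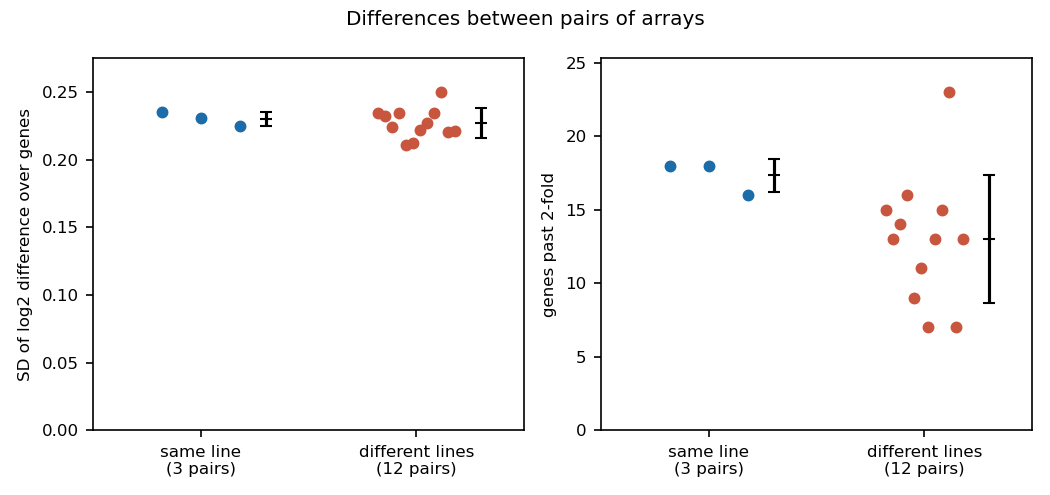
SD over genes of the log2 difference (left) and number of genes past 2-fold (right) for each pair of arrays, as points for the 3 pairs of the same labelled line and the 12 pairs of different lines, with the mean and SD in black. The SD over genes had a mean of 0.231 in same-line and 0.227 in different-line pairs.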

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

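Alternatives that leave out the 44 discordant probes were added after the data were seen, and the others were planned. The count of 5 genes with CRP became 8 with no background correction (floor 16), 2 with every probe on its own, and 0 with no filter on dim probes, with a detection p under 0.05 as the filter, with the series matrix values, without the 44 discordant probes, and with series matrix values without those 44. Leaving out a line gave 0 (without ARP-1, and without MM.1S) to 5 (without U266), and LOC100133076, called without U266, was the single gene on a concordant probe called with CRP by any of these alternatives. With no replicate block, 4 genes were called, FOXD4L1 and 3 of the 5, without CCL3 and ZNF223. The other alternatives gave 5 to 7. The matrix log2 changes of the 5 genes, taken with 16 added to each value, lay between 0.47 and 0.93, none past the threshold. The added 16 shrinks changes of low values. Without it, mean processed values in control and CRP cells were 6.62 and 15.4 for KAT7, 24.4 and 49.6 for ZNF134, 27.4 and 67.1 for ZNF2, 26.0 and 60.2 for ZNF223, and 1049 and 1555 for CCL3. The cause of these shifts was not tested, except that leaving out the 44 removes the called genes themselves. No list was called under any alternative by camera or by fry's directional test.

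For the lines, the count of 0 became 3 with normexp (offset 50), 4 with no background correction, 3 with genes detected on all 6 arrays and 3 with an intensity trend (CCL3, ZNF223 and MIR1974 in each, with MTF2 as the fourth), and stayed at 0 without any single array. Within ARP-1, MM.1S and U266, genes past 1.5-fold numbered 44, 31 and 35 with normexp, 79, 63 and 74 with no background correction, 778, 752 and 892 with no filter, 162, 120 and 133 with genes detected on all 6 arrays, 789, 756 and 885 with a detection p under 0.05, and 51, 40 and 57 past 2-fold. Counts that include dim genes thus rest on signals near background. The 24 concordant genes named for a shared direction kept the sign of their mean change with normexp, no background correction, cyclic loess, median scaling and the series matrix values, none past the threshold. Leaving out a line, the block or other probes cannot turn that sign. Splits of the 6 arrays are too few (10) for a share under 0.05: the real split called 5 genes and the highest other 0, with 1 split calling as many, and all 10 splits called 0 lists.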

Other observations

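All tests of explanations here were chosen after the results were seen. Of the list of myeloma oncogenes, 4 genes picked after their values were seen had like levels on the arrays of each label. CCND2 (cyclin D2) had mean log2 levels of 12.9 on arrays labelled ARP-1, MM.1S and U266, the homing integrin gene ITGB7 had 14.3, 14.4 and 14.3, the chemokine receptor gene CCR1 9.74, 9.77 and 9.91, and the kinase gene NUAK1 9.80, 9.75 and 9.73. No contrast between lines passed the threshold for these genes.

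Arrays labelled as 3 lines differed no more between lines than within a line. Quantile normalization did not remove line differences, since un-normalized signals of bright probes differed by an SD of 0.161 between lines and 0.162 ± 0.0111 within a line. Too few arrays cannot be set aside for differences under 2-fold in few genes. In simulated data with 200 of 10959 genes changed, 0% of line differences of 1.5-fold were recovered. Such differences in many genes would raise the number with an unadjusted p under 0.05. That number was 535 in the F test, and 445, 527 and 613 in the contrasts, where 548 would come by chance. A typical line difference had a 95% interval of 1.22-fold either way. These values argue against differences of 1.5-fold in many genes. Past 2-fold, arrays of different lines had on average 13 genes, no more than the 17.3 of same-line arrays. Same-line arrays also differ in treatment, so that the 17.3 includes any difference with CRP. Labels exchanged among arrays of 3 different lines would leave some pairing far more alike, but the lowest mean SD of the 15 pairings was 0.219 against 0.231 for the labelled one. RNA of a single line on all 6 arrays is a candidate explanation that stays open, with the labelled pairing at rank 11 of 15 from the most alike, and no biological explanation was tested.

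The genes called with CRP all sat on probes whose deposited values did not belong together, and normalization of whole arrays, which keeps the order of probes, is not the reason, since 189 of the 264 values broke that order. Higher transcript levels by the size of the signals would lower the detection p, but over the 36 discordant probes with a p above 0 the log2 change it implies had a median of 0.0126 (SD 0.135) against 1.06 for the signals. Of the called genes, these included KAT7, with implied changes of -0.25 to -0.11 against 1.33 to 2.25 by signal. The other was ZNF134, with 0.08 in ARP-1 and -0.07 in U266 against 1.16 and 0.87. For ZNF2 and ZNF223 the detection p allowed a change of at most 0.42 in U266, against 0.62 and 0.95 by signal. In ARP-1 and MM.1S their p of 0 on the CRP arrays sets no upper end, so larger changes there stay open. With the CRP signals taken as deposited there, and control cells at the bottom of the range of their p, the change was at most 0.28. Higher levels of CCL3 stay open, since 0 of its 6 signals lay outside the range of their p, which has no upper end at its p of 0, and so does a separate route of these probes into the tables: 15.2% of their processed values occurred on another array, as quantile normalization brings about, against 100% of other probes' values. A lowering of signals by whole multiples of 10 after the detection p was set is a candidate explanation, since 96 of 123 signals lay a whole multiple of 10 units from the range of their detection p, and how this came about cannot be read from the tables.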
